A study of Arabidopsis thaliana with 28 samples.

How the data were processed

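RNA was extracted from aerial parts of 6 day-old seedlings and made into stranded mRNA libraries, per the labels' protocols, with 3 libraries of wild-type Col-0 and 3 of caa39. Samples were grouped by the genotype given in their labels. Of the same series, the immunoprecipitated chromatin, input and bisulfite libraries were not analysed here. The submitters' processing notes name FastQC 0.10.1, Bowtie2, edgeR 1.12.0 and the TAIR10 build, without saying what each was used for. How reads were assigned to element families, how reads matching several copies were treated, and which program gave the p-values are not given in the sources used here. A family sums reads of near-identical copies, so reads may be shared between related families.

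The table used is the authors' own comparison of the genotypes, with 84 entries: 83 named families and 1 entry of unassigned elements, which stayed out of all tests and held 28.4% of the listed reads. The deposited signal of each group is the authors' mean of normalised read counts, per the file headers. The deposited ratio, or fold, is the caa39 mean over the wild-type mean, and the deposited log2 value is its logarithm, which held within 1e-09 in all 84 entries. The authors' deposited p-value is given raw and adjusted, and the largest adjusted value is 0.0499, so families that did not pass are not listed. The ratio of adjusted to raw p-values gave whole ranks, within a relative tolerance of 1e-08, in 74 entries if 23918 tests had been made, against 37 for the next best number of tests. In 4 entries (ATCOPIA21, HELITRONY2, ATCOPIA38B and ATCOPIA79) the deposited wild-type signal is exactly 1 while the overall mean gives a wild-type mean of 0, so the deposited folds of these families are not reported as measured folds. They enter the ranking of the naming rule, the plot and the tests across families as deposited.

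Library counts were solved from the deposited means after the data were seen. A mean of 3 normalised counts is a sum of 3 whole read numbers, each times a constant of its library, and the means carry 15 digits. All 78 distinct wild-type means and all 84 caa39 means had exactly 1 solution in whole reads, within a relative tolerance of 1e-14 and an absolute tolerance of 2e-13. For caa39, 3 sets of constants were found, and the set with the smallest spread between libraries was taken (median coefficient of variation 8.00%, against 70.7% for the next). For the wild type 1 set was found, with 6.76%. No mean could be solved after a small random shift, and the geometric mean of the 6 size factors was 1.00. On simulated data the solver returned all 3 counts in 84 of 84 entries for each group. Size factors were 0.943, 0.868 and 0.823 for wild-type libraries a, b and c, and 1.37, 1.21 and 0.914 for caa39 libraries a, b and c. One read was therefore worth 0.732 to 1.22 normalised counts. Solved libraries cannot be tied to replicate numbers. All SDs are of these solved counts divided by size factors. Totals cover the listed families and are not sequencing depths of the libraries, which are not given in the sources used here.

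The main calls are those of the authors' deposited table at an adjusted p below 0.05. As an added test, limma 3.58.1 in R 4.3.3 was run on log2 of the solved normalised count plus a pseudocount of 0.5, with Benjamini-Hochberg adjustment over the 83 families. On that scale folds of families with few reads depend on the pseudocount. The families had been selected for significance on these libraries, so this adjustment is not independent evidence. On simulated data with 83 families limma called 80% of 20 families at a true 2-fold change, all 20 at 4-fold, and 1 of 43 unchanged families. All simulated families had the same dispersion, and 43 were unchanged, while the listed families had been chosen as changed. These rates therefore need not hold for the real libraries. Other tests used Python 3.11.15 with scipy 1.17.1, numpy 2.4.6 and pandas 2.3.3, and plots used matplotlib 3.10.9: exact binomial and Fisher's exact tests, and permutation tests with 100000 resamples, all two-sided. Ratios on few reads have exact 95% intervals from the reads of each group over its summed size factors. A group with 0 reads was given a floor of 3 reads over the group. Bounds against that floor take the reads of the other group as exact, so they are not 95% limits.

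The tests, their thresholds, the alternatives and the families to be named were fixed before the data were examined. The rule named the 10 families with the largest rise and the 10 with the largest fall among those whose caa39 libraries all lie on the same side of all wild-type libraries. It also named the 5 families with the smallest adjusted p, and the listed members of a fixed set of well-known families: ATCOPIA93, ATCOPIA78, ATCOPIA21, ATCOPIA13, ATGP1, ATGP3, ATHILA, META1, VANDAL21, ATMU1, ATENSPM3, SADHU, ATLINE1, TSI, SDC and ROMANIAT5. It gave 28 families, and of the set ATGP1, ATGP3, META1, ATMU1, ATENSPM3, SADHU, TSI, SDC and ROMANIAT5 are not among the listed families. Other families in the text were chosen after their values were seen. The superfamily groups were fixed as well, except for 1 of the 11 groups tested, and no Sadhu family is listed. That group, of the unplaced DNA families ATDNA12T3A and RP1_AT, was added. RathE2_cons, whose deposited superfamily is its own name, was placed with SINE. The planned tests of superfamily composition, chromosomal position and fold change by position were not run, because they need the families that did not pass and positions of copies. The tests of direction within superfamilies, limma and the scaling to listed reads were added after the data were seen. Leaving out each library had been planned for values per library, and was done on the solved ones.

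Alternatives were an adjusted p below 0.01, a 2-fold minimum, Bonferroni adjustment over the listed families only, and other pseudocounts (0.1 and 1). Further ones were a minimum mean of 10 normalised counts, scaling to listed reads, subsets of families and the leaving out of each library. A count model such as edgeR was not run on the solved counts.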

Results

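RNA was sequenced from aerial parts of 6 day-old Arabidopsis thaliana seedlings, with 3 libraries of the wild type Col-0 and 3 of caa39, a mutant affecting topoisomerase VI, an enzyme that passes DNA strands through each other. The RNA libraries are biological replicates per the series design. Expression was given for families of transposable elements, each family summing copies dispersed over the genome, so no coordinates are attached to the values. Wild-type libraries a, b and c held 18997, 18444 and 16301 reads in the 83 named families, and caa39 libraries a, b and c held 22681, 20205 and 14609. With the entry of unassigned elements the listed reads were 26678, 25314 and 22924 in the wild type and 31566, 27839 and 20791 in caa39. The letters order the libraries by size factor and are not replicate numbers. Chromatin immunoprecipitation and bisulfite libraries of the same series were not analysed here.

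The first comparison asked which transposable element families differed in expression between caa39 and the wild type, and in which direction. Families went both ways: 40 rose and 43 fell in caa39 in the authors' deposited table, which lists 83 named families with an adjusted p below 0.05. The 4 listed ATHILA retroelements, 6 of 7 ATENSPM DNA transposons and VANDAL20 rose, while 11 of 14 Helitrons fell. Of the 25 Copia families 12 rose and 13 fell, among the latter ATCOPIA62, ATCOPIA74, ATCOPIA50 and ATCOPIA12. No superfamily passed a test of its direction against the other listed families (Fisher's exact test, adjusted p of 0.286 for En-Spm and for Helitron). VANDAL20, a MuDR-like DNA transposon family, rose 7.87-fold with an adjusted p of 1.04e-127 in the authors' deposited table. ATCOPIA62 fell to 0.148 of its wild-type level with an adjusted p of 3.26e-76 in the authors' deposited table. The library counts solved from the group means gave VANDAL20 119.5 ± 8.92 normalised reads in the wild type and 941 ± 46.1 in caa39 (SD, n = 3 each). For ATCOPIA62 they gave 611 ± 20.5 and 90.6 ± 7.02 (SD, n = 3 each).

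The split of 40 against 43, or 48.2% rising, did not differ from an even division (exact binomial p = 0.826, two-sided, across families, which are not independent replicates). The table lists only families chosen for significance on these libraries, so this share describes the list. How many families were tested is not given in the sources used here, so the 83 cannot be given as a share of them. Of the 23918 tests implied, 35.7% ranked up to the listed family with the largest p-value, so at least that share passed an adjusted p of 0.05. The median log2 fold change in the authors' deposited table was 2.20 among families that rose and −0.95 among those that fell. With the 4 families that had no wild-type reads set to their bounds against a floor of 3 reads, the median rise was 2.18. At least 2-fold changes were listed for 30 families that rose and 21 that fell in the authors' deposited table. Median expression was 51.2 normalised reads in families that rose and 151 in those that fell. Families with fewer reads pass only with larger folds, so these sizes describe the list as well. In 82 of 83 families all 3 caa39 libraries lay on the same side of all 3 wild-type libraries. Chance gives this separation in 10% of unselected families, which is no baseline here because the families were listed for passing a test between these libraries. ATCOPIA70 was the exception, with 36 reads in wild-type library c and 0 in the other two wild-type libraries. Applied to the solved library counts, limma passed an adjusted p of 0.05 in 81 of 83 families, 39 of them higher and 42 lower in caa39. The families outside were ATCOPIA95 (adjusted p = 0.0724) and ATCOPIA70 (adjusted p = 0.719). In the 4 families with no wild-type reads every wild-type value in limma is the pseudocount alone, with no spread, which makes their p-values small. For ATCOPIA79 the raw p was 1.81e-05 in limma and 0.0098 in the authors' deposited table.

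Scaling each library to its total of listed reads, unassigned elements included, corresponds to a shift of the group totals of −0.31 on the log2 scale. In limma it raised log2 fold changes by a median of 0.31, and by as little as 0.12 in families with few reads. This turned the direction of ATCOPIA4 alone, which stood at 0.825 of the wild type in the authors' deposited table. On that scale limma passed 69 families, 40 higher and 29 lower in caa39.

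**Figure D1:**
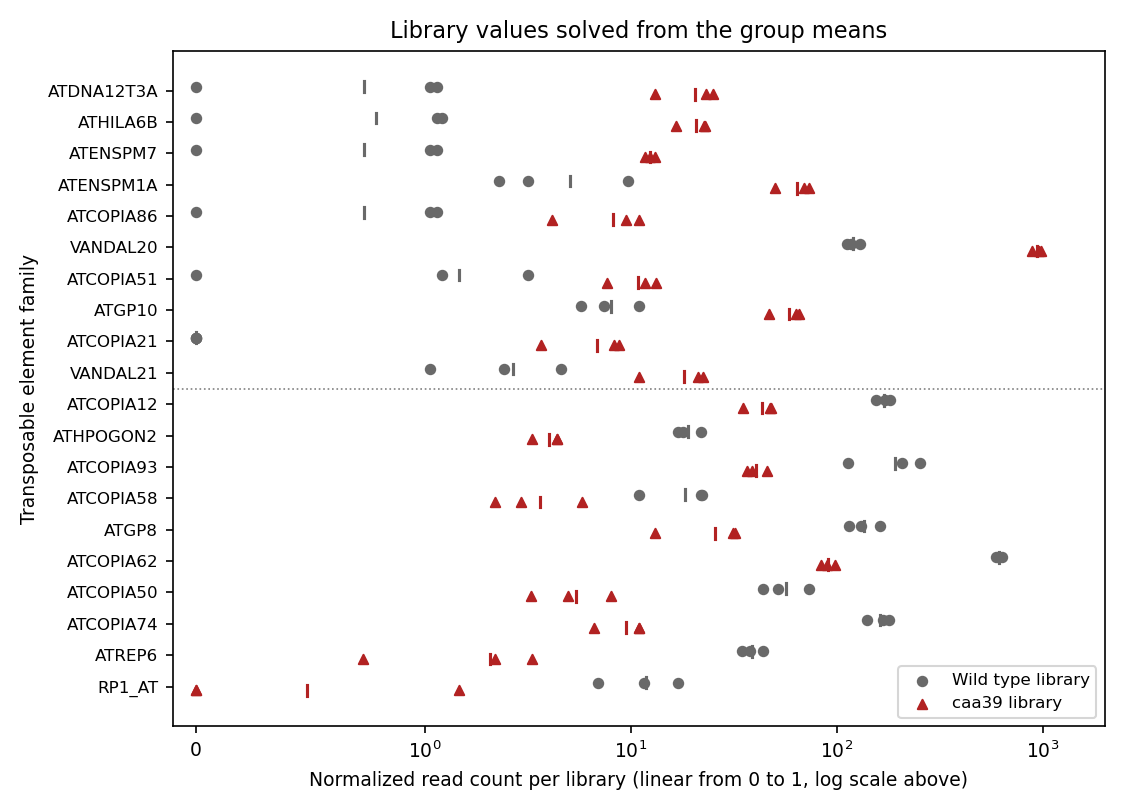
Normalised read count in each of the 3 wild-type (circles) and 3 caa39 (triangles) libraries for the 10 families with the largest rise and the 10 with the largest fall, on an axis that is linear from 0 to 1 and logarithmic above; short bars mark group means. The families were picked so that the caa39 libraries lie on the same side of all wild-type libraries; group means of VANDAL20 are 119.5 and 941.

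Among the largest rises, several families were near silence in the wild type. ATDNA12T3A had 2 wild-type and 69 caa39 reads, a ratio of 26.1 with an exact 95% counting interval of 6.94 to 219. ATHILA6B had 2 and 72 reads, a ratio of 27.2 with an interval of 7.26 to 229. For ATENSPM7, with 2 and 43 reads, the ratio was 16.2 with an interval of 4.23 to 138. ATCOPIA86, with 2 and 28 reads, gave 10.6 with an interval of 2.67 to 91.6. ATCOPIA21 had 0 reads in the wild type and 23 in caa39. Against a floor of 3 reads over the group this gave a bound of 5.79-fold higher. It takes the caa39 reads as exact and is not a 95% limit. Without wild-type library a that bound was 3.71, since the floor then rests on fewer libraries. ATENSPM1A rose 12.7-fold, ATCOPIA51 7.42-fold, ATGP10 7.32-fold and VANDAL21, the family of the mobile element Hiun, 6.73-fold in the authors' deposited table. Single wild-type libraries moved some of these folds: 23.5 for ATENSPM1A without wild-type library c, 17.9 and 4.95 for ATCOPIA51 without libraries a and b, and 10.4 for VANDAL21 without library b. The following ratios are of mean normalised counts, not of pooled reads. ATHILA6B stood at 26.3 with all libraries and 17.5 without wild-type library a. ATCOPIA86 stood at 11.1 with all libraries and 7.41 without wild-type library c. For ATDNA12T3A it was 27.8 with all, 18.5 without wild-type library c and 38.7 without b. For ATENSPM7 it was 16.8 with all, 11.2 without wild-type library c and 23.4 without b. The counting intervals cover counting error only.

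Among the largest falls, ATCOPIA74 went from 162 ± 20.1 to 9.51 ± 2.51 normalised reads and ATCOPIA50 from 56.5 ± 15.5 to 5.43 ± 2.42 (SD, n = 3 each). ATREP6, a Helitron family, went from 38.8 ± 4.64 to 2.08 ± 1.29, on 102 and 7 reads (SD, n = 3 each). RP1_AT had 31 reads in the wild type and 2 in caa39, a ratio of 0.0487 with an exact 95% counting interval of 0.00565 to 0.191, and both caa39 reads came from library a. The remaining falls in the authors' deposited table were ATGP8 at 0.188 of the wild type, ATCOPIA58 at 0.198, ATHPOGON2 at 0.212 and ATCOPIA12 at 0.256. ATCOPIA93, the family of the mobile element Evadé, stood at 0.211 of the wild type in the authors' deposited table. Its wild-type libraries held 253, 114 and 208 normalised reads and its caa39 libraries 36.6, 38.9 and 46.0. The LINE family ATLINE2 fell to 0.402 (adjusted p = 7.55e-31), and ATLINE1_6 to 0.678, in the authors' deposited table.

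ATCOPIA78, the heat-responsive ONSEN family, rose 1.81-fold with an adjusted p of 0.0495 in the authors' deposited table. ATCOPIA13 rose 1.91-fold with an adjusted p of 0.0364 in the same authors' deposited table. In limma, with log2 fold changes of 0.88 and 0.92, both lost their call when certain libraries were left out, which also leaves fewer libraries to the test. For ATCOPIA78 the log2 fold change was 0.93 without caa39 library b (limma adjusted p = 0.0512) and 0.74 without caa39 library c (limma adjusted p = 0.0769). For ATCOPIA13 it was 0.65 and 1.03 without wild-type libraries a and c (limma adjusted p = 0.0967 and 0.0521), and 0.79 and 0.77 without caa39 libraries a and b (limma adjusted p = 0.109 and 0.110).

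The next comparison grouped the families by superfamily. All 4 listed ATHILA families, members of the Gypsy retroelements, rose by 4.52-fold to 26.3-fold in the authors' deposited table. The lower end was ATHILA2, which went from 22.5 ± 4.27 to 101.9 ± 21.1 normalised reads, and ATHILA6A went from 30.2 ± 6.77 to 181 ± 11.8 (SD, n = 3 each). ATHILA3 went from 18.6 ± 8.08 to 87.0 ± 3.35 (SD, n = 3 each). Of the 7 En-Spm (CACTA) families 6 rose, and their summed normalised count went from 249 ± 10.7 to 1167 ± 84.3 (SD, n = 3 each). ATENSPM11 made up 55.9% of that sum in the wild type and 73.0% in caa39, and without it the sum went from 109.9 ± 6.13 to 315 ± 22.7 (SD, n = 3 each). Of the 14 Helitron families, rolling-circle DNA transposons, 11 fell, and their sum went from 2974 ± 152 to 1911 ± 120 (SD, n = 3 each).

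Copia families divided into 12 that rose and 13 that fell, and their sum went from 6629 ± 99.8 to 5160.1 ± 186 (SD, n = 3 each), with 44.6% of it from ATCOPIA4 in the wild type and 47.2% in caa39. Gypsy families numbered 7 that rose and 4 that fell, and MuDR families likewise 7 and 4. The MuDR sum went from 2195 ± 27.6 to 2526 ± 67.3, while the Gypsy sum went from 2578 ± 167 to 2285 ± 90.5 (SD, n = 3 each). Single families set both directions: without VANDAL20 the MuDR sum went from 2075 ± 20.7 to 1585 ± 35.6, and without ATLANTYS2 the Gypsy sum went from 1454 ± 81.8 to 1586 ± 46.9 (SD, n = 3 each). Of 4 LINE families 3 fell, and the sum went from 1964 ± 21.5 to 1153 ± 11.3 (SD, n = 3 each). Of 4 hAT families 3 fell, and the sum went from 2715 ± 800.2 to 1266 ± 21.6, with 71.9% of it from ATHAT10 in the wild type and 57.1% in caa39 (SD, n = 3 each). Without ATHAT10 the hAT sum went from 762 ± 73.0 to 543 ± 48.1 (SD, n = 3 each). ATHAT10 held 2953 normalised reads in wild-type library b against 1462 and 1442 in the other wild-type libraries, and its ratio of 0.370 was 0.498 without library b. SINE, Harbinger and the unplaced DNA families each had 1 family that rose and 1 that fell, and the only Pogo family fell. On the scale of listed reads the Gypsy and Harbinger sums turned upward, with log2 ratios of 0.14 and 0.23. The SINE sum turned as well, from −0.26 with separated libraries to 0.04 with overlapping ones. The Copia sum stood at −0.05, also with overlapping libraries. The libraries of the Harbinger sum overlapped before that scaling. On that scale the log2 ratios of the En-Spm, MuDR, Helitron, LINE and hAT sums were 2.54, 0.51, −0.33, −0.46 and −0.79. The direction of a superfamily's families was compared with that of all other listed families by Fisher's exact test, two-sided, over 11 groups. Helitron had p = 0.0395 and En-Spm p = 0.0520 in these exact tests, and both had an adjusted p of 0.286, so no superfamily passed. LTR retrotransposons (Gypsy and Copia, 36 families) had a median log2 fold change of 0.62 and the 47 other families −0.47, a difference of 1.09 that a two-sided permutation test did not separate from 0 (p = 0.417).

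**Figure D2:**
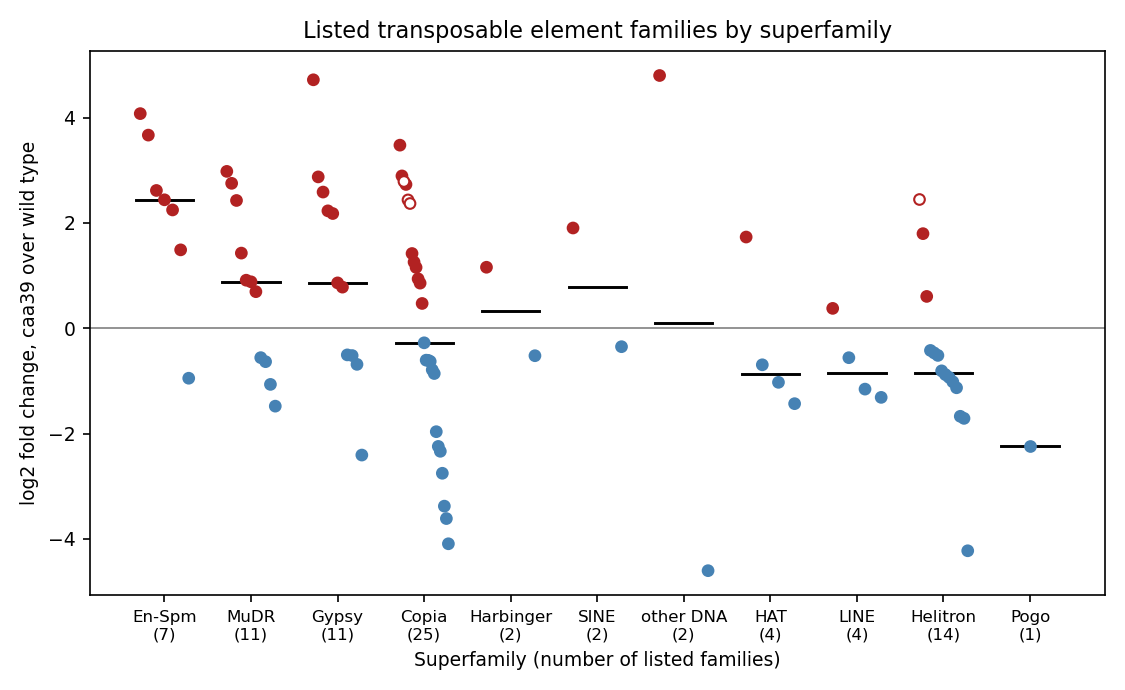
Log2 fold change of caa39 over wild type, from the authors' deposited table, for each of the 83 families grouped by superfamily; bars mark medians and open circles the 4 families with no wild-type reads. Of the En-Spm families 6 lie above 0 and 1 below, and of the Helitron families 3 lie above and 11 below; ATCOPIA4, nearest to 0 among the Copia families that fell, turns direction when libraries are scaled to listed reads.

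The last comparison set fold change against expression level. The summed normalised count of the 83 named families went from 20398 ± 751 in the wild type to 16433 ± 392 in caa39, a change of −19.4% (SD, n = 3 each; exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). Abundant families such as ATCOPIA4, HELITRON1 and ATLANTYS2 were lower in caa39: of the 20 families with a mean of at least 300 normalised reads 18 fell, although on the scale of listed reads, a total made up largely of these families, ATCOPIA4 turned upward and 9 of the 18 were no longer past the threshold in limma. The exceptions among the 20 were VANDAL20 and ATENSPM11. Of the 16 families with a mean below 20, among them ATHILA6B and ATENSPM7, 11 rose and 5 fell. Both limits were set after the values were seen.

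Across the 83 families, which are not independent replicates, log2 fold change fell with log2 mean expression (Pearson's r = −0.27, permutation p = 0.0131, adjusted p = 0.0224; Spearman's rho = −0.25, permutation p = 0.0244, adjusted p = 0.0325). Without the 2 families farthest from the median expression the coefficients were −0.26 (permutation p = 0.0207) and −0.23 (permutation p = 0.0374). At an adjusted p below 0.01 Spearman's rho was −0.21 and no longer passed (permutation p = 0.0998). The coefficient was 0.62 within the families that fell and −0.50 within those that rose, and −0.60 for the size of the log2 fold change in either direction. A family with few reads passes a significance threshold only with a large fold, so the list itself can give the signs of these 3 values. How much of them it gives was not tested, and they are not read as a relation. The coefficients over all 83 families come from the same list and only describe it. Their permutation p-values allow any fold at any expression level, which the threshold does not. Adjustment was over the 12 coefficients computed.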

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

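The tests on solved library counts, the scaling to listed reads and the split of the relation among families that fell were chosen after the results were seen. The number of families past the threshold was 83, with 51 left at a 2-fold minimum and 62 at an adjusted p below 0.01. With Bonferroni adjustment over the 83 listed families 52 were left. That adjustment did not cover the 23918 tests implied, which would be stricter. Fewer is what stricter limits construct. With limma it was 81, between 69 and 81 under other pseudocounts, a minimum mean and scaling to listed reads, and between 76 and 81 with a library left out. Scaling to listed reads gave 40 families higher and 29 lower in limma, against 39 and 42. The share that rose was 48.2%, and 58.8% among families changed at least 2-fold, on the other side of an even division (exact binomial p = 0.262); neither share passed its test. Among families above the median expression it was 34.1% (exact binomial p = 0.0596), and it ran from 48.2% to 49.4% with a library left out. That range was narrow by construction, since only ATCOPIA70, whose libraries overlap, could turn direction there. The correlation of fold change with expression turned from −0.27 to 0.62 (Spearman from −0.25 to 0.61) within the families that fell. Splitting a list chosen for significance by direction can give such a turn, but how much of it was not tested. Spearman's rho was −0.21 at an adjusted p below 0.01 (permutation p = 0.0998), the cause of which was not tested. The LTR contrast kept its sign and stayed short of its threshold, from 0.10 to 1.25. For the 28 named families 297 of 303 alternative values kept direction and call, and 0 changed direction. The 6 that lost the call were all of ATCOPIA13 or ATCOPIA78 with a library left out. In all 28 the caa39 libraries lie on the same side of all wild-type libraries. Leaving out a library or changing the pseudocount could therefore not turn a direction. No paired analysis was possible because the table gives group means and the solved libraries carry no replicate numbers. Tests of composition and position, and count models, were not run; counting each family once changes nothing, since each entry is a family. Depth limits the families with 0 to 3 reads in a genotype, whose folds have wide intervals.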

Other observations

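All tests weighed in this part were chosen after the results were seen.

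Listed subfamilies that share a name and a number formed 4 sets of 10 families, each with a single direction. ATDNAI27T9A, ATDNAI27T9B and ATDNAI27T9C, MuDR families, rose by 1.84-fold to 5.37-fold in the authors' deposited table. HELITRONY1A, HELITRONY1B and HELITRONY1C fell to between 0.314 and 0.571 of the wild type in the authors' deposited table. ATREP10A and ATREP10D fell to 0.457 and 0.699, and ATHILA6A and ATHILA6B rose, in the authors' deposited table. Of the ATREP families, non-autonomous Helitrons, 6 of 7 fell, and ATREP15 rose 3.47-fold in the authors' deposited table. Directions drawn without regard to the name gave as many such sets with a permutation p of 0.0145, which decides nothing, because the sets were defined after the directions were seen. Some wider name groups were divided: of the ATGP families 2 rose and 2 fell, of ATLANTYS 1 and 2, and of VANDAL 3 and 1. Others were not, as all 4 ATHILA families rose and all 3 ATLINE families fell.

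Other families outside the naming rule changed strongly. ATRE1, a Copia family outside the 10 largest rises because ATCOPIA21 ranked above it by its deposited fold, went from 65.5 ± 19.7 to 435 ± 27.2 normalised reads, and ATHATN3, of the hAT group, from 36.1 ± 7.78 to 119.8 ± 11.4 (SD, n = 3 each). HELITRONY2, ATCOPIA38B and ATCOPIA79 had 0 wild-type reads. Against a floor of 3 reads over the group their bounds were 4.53-fold, 4.78-fold and 4.53-fold higher in caa39, with the caa39 reads taken as exact. The bound of ATCOPIA38B was 2.31 without caa39 library b, which held 13 of its 19 reads, and without wild-type library a the bounds were 2.91, 3.07 and 2.91. ATENSPM10, with the largest adjusted p in the authors' deposited table, has rank 8546 of the 23918 tests implied, or 35.7% of them. With 84 entries listed, those tests covered far more than these entries, and what else they covered is not given in the sources used here.

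Of the 20 families with a mean of at least 300 normalised reads, 18 fell, and the listed families together changed by −19.4%. The entry of unassigned elements, which is not among them, changed by −18.8%, from 8035 ± 115 to 6527 ± 226 normalised reads (SD, n = 3 each). That entry was itself listed for passing, so it is no unchanged reference, and an offset or lower expression could give its fall. A scaling offset between the genotypes was tested by scaling each library to its listed reads: 9 of the 18 still fell past an adjusted p of 0.05 in limma, 9 did not, and ATCOPIA4 turned upward. That count decides nothing, since the 18 families make up 78.8% of the wild-type sum of named families and the scaling takes up much of their fall by construction. The folds of the 18 families, from −0.28 to −2.75 on the log2 scale, differed far beyond their errors (Cochran's Q = 601 on 17 degrees of freedom, with limma's standard errors), which a single factor as the whole cause does not give; an offset as part of the cause cannot be told apart from lower expression, because no unchanged families are listed. The selection of small changes in abundant families was tested among families changed at least 2-fold, where those that fell were more abundant by a median of 1.415 on the log2 scale (permutation p = 0.214), which leaves it open too. Of abundant families changed less than 2-fold 14 of 14 fell, against 8 of 18 less abundant ones.

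ATCOPIA70 and ATHAT10 each stood apart in a single wild-type library. ATCOPIA70 had 36 reads in library c and 0 in libraries a and b, and without library c the wild type had 0 reads against 4 in caa39, so that no fall was left. ATHAT10 had 2953 normalised reads in library b against 1462 and 1442, and its ratio was 0.370 with all libraries and 0.498 without library b. In the median family, library c differed from the other libraries by 0.0378 (log2) and library b by −0.0342. After division by size factors, most listed families of these libraries thus showed no shift in the same direction. That division could have taken out a shift shared by a whole library, so the medians cannot speak on it. A median cannot show a library whose families deviate in both directions, so that cause was left open. Against counting noise the reads gave an exact multinomial p of 6.38e-19 for ATCOPIA70 and a chi-square p of 4.88e-147 for ATHAT10, which decides nothing, because single libraries are set against counting error; ATCOPIA93, ATHATN1, ATREP4 and ATREP10D, 4 of 77 other families with wild-type reads, also had a chi-square p below 0.001. These 4 families were all lowest in wild-type library b, where ATHAT10 was highest. In the order named, they held 114, 446, 62.2 and 334 normalised reads there. The means of the other wild-type libraries were 231, 563, 111 and 433. No biological explanation was tested, because no group of the design divides the wild-type libraries. ATCOPIA95 likewise rested on caa39 library b, with 68.6 normalised reads against 26.4 and 20.8, and its ratio of 2.39 was 1.46 without it.

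The number of families past the threshold in limma was 81 for the real split and at most 0 for the other splits. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many, the real one, and 10 are too few splits for a share under 0.05. The families had been listed for passing a test on the real split, so these counts say nothing on chance.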
